A study of Mus musculus with 2 samples.

How the data were processed

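Mononuclear cells of wild-type mouse quadriceps, taken at 2 h or 9 h after barium chloride injury and cryo-preserved, were sequenced as 1 droplet library per time with a target of 5000 cells each. The deposited files hold counts, as UMIs per gene and cell barcode, which the authors made with Cell Ranger 5.0.0 on mm10 per the submitters' processing notes. The annotation release, the aligner settings, the number of animals per library and the sequencing batches were not given in the sources used here. The files listed 5729 barcodes with 28635763 UMIs at 2 h and 8790 barcodes with 36042307 UMIs at 9 h, and every barcode had at least 500 UMIs. Of the 32285 genes, 32235 (99.8%) were matched by identifier to the GENCODE M21 mouse annotation, which gave positions on mm10.

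Cells with under 200 genes or 500 UMIs were removed (513 at 2 h and 264 at 9 h), then cells with a mitochondrial share over 20% (316 and 379), which left 4900 cells (85.5%) and 8147 cells (92.7%). Median genes per kept cell were 1622.5 and 870, and median mitochondrial shares 3.52% and 1.88%. Scrublet called 6 doublets at 2 h (0.122%) and 0 at 9 h, under the 0.5% below which its calls were set aside, so all kept cells were used. The planned run without doublet removal is therefore the same as the values reported. A further planned run left out the cells with the highest doublet scores (225 and 573, at 0.8% of cells per 1000 barcodes). The libraries were clustered together without batch correction: UMIs scaled to 10000 per cell, log transformed, 2000 variable genes, scaled values limited to 10, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 with seed 0. Analyses used Python 3.11.15, Scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and TMM scaling used edgeR 4.0.16 in R 4.3.3.

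Clusters were named from 20 marker lists. A cluster took the class with the highest marker score if at least 3 of its markers were each detected in at least 10% of the cells and the score was at least 1.5 times the next, and if its 10 leading genes held no more markers of another class than of its own. Clusters 7 and 18 stayed unnamed. Cluster 7 scored as FAP with all 15 FAP markers, but its leading genes held 1 glial marker, Scn7a, and no FAP marker. Scn7a was also carried by FAP-like clusters, so this marker did not set glial cells apart from FAP-like cells here. Counting cluster 7 as FAP-like was added as an alternative after the data had been seen, and the choice to leave it out as the main form was settled with both sets of values known. T and NK cells were taken as 1 class, and monocyte-like and macrophage-like cells were compared together and apart.

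Shares of cells carry exact (Clopper-Pearson) binomial intervals, levels carry exact Poisson intervals on the summed UMIs, and ratios between the times carry exact conditional binomial intervals, all at 95%. They cover counting error only, and no interval covers differences between animals or libraries. Intervals of levels, of shares of UMIs and of ratios treat each UMI as independent. They leave out the spread between cells and are too narrow where few cells hold most of the UMIs. With 1 library per time no test across samples was made. Shares of cells with a UMI were counted after thinning each cell to 1000 UMIs, and also at 2000 UMIs and unthinned. A gene without counts in 1 library was given a bound against a floor of 3 counts. Log2 ratios used a pseudocount of 10 CPM.

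Genes were compared in each class with at least 100 cells in each library. Genes with at least 100 UMIs over both libraries counted as measured. Before the data were examined, the rule for named genes was set: a level of at least 100 CPM in 1 library and, in the library where it is higher, at least 20% of the level over all kept cells, leaving out mitochondrial, ribosomal protein and haemoglobin genes and unnamed gene models. The 12 highest and 12 lowest log2 ratios were named in FAP-like cells and in monocyte-like and macrophage-like cells together, 5 and 5 in the other classes, and Ccl2, Ccl7 and Ccr2 were read in each class; in the smaller classes some named genes are left out of the text for length. Results for a few genes are not reported. From each of 26 gene lists written in advance, the members given are those with the highest level or the largest ratios. Each list's median log2 ratio was ranked among 10000 random lists of the same size drawn from the 50 genes nearest in level to each member, as a description of these libraries.

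The ratio and list steps were tested on simulated data with known answers at the depth of the FAP comparison (10177 genes measured). With 50 genes per simulated fold, the interval held the true fold for 98% of genes at 0.25, 96% at 0.5, 98% at 2 and 96% at 4, and for 96% of 500 unchanged genes. The simulated counts were Poisson draws of summed UMIs, the model that the intervals assume. This coverage therefore checks the computation only, and spread of UMIs between cells was not simulated. A list of 15 genes raised by 2 times had a median log2 ratio of 0.91 and percentile 100. Of 100 lists of unchanged genes, 95 fell within the central 95% of random lists.

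The alternatives were a mitochondrial limit of 10% or none, at least 500 genes and 1000 UMIs per cell, removal of the cells with the highest doublet scores, resolutions 0.5 and 2, each library clustered alone, TMM scaling, totals without mitochondrial, ribosomal protein, haemoglobin and free RNA genes, means over cells, a pseudocount of 1 CPM, no filter on low counts, and other thinning depths. Neighbours from the other library were counted with 100 cells per library thinned to 1000 UMIs, 10 draws, 1000 genes, 10 components and 15 neighbours, and gene order was examined with 10000 shuffles of gene order. RNA carried over from FAP-like or neutrophil-like cells was estimated, after the differences had been seen, as the source level times the ratio of Dcn or S100a8 between the class and its source.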

Results

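The series asked whether CCL2, the chemokine that draws monocytes into injured tissue, comes from fibro-adipogenic progenitors (FAPs), the mesenchymal cells between muscle fibres. Droplet single-cell RNA sequencing was done on mononuclear cells of wild-type C57BL/6J mouse quadriceps injected with barium chloride (100 µl, 1.2% w/v), a salt that kills muscle fibres. There was 1 library from 2 h and 1 library from 9 h after the injection, so no difference between the times below could be checked against replicates, and no test across animals was possible. The 2 h library kept 4900 cells with a median of 4519 UMIs (unique molecules) and 27598413 UMIs in all. The 9 h library kept 8147 cells with a median of 2327 UMIs and 35127600 UMIs in all. Cells were grouped by clustering and by marker genes, and each group is called "like" its cell type because no sort was available. Levels are given in CPM (a gene's UMIs in a group's cells, with the group's UMIs scaled to a total of 1000000), intervals are at 95% and cover counting error only, and percentiles of gene lists refer to 10000 random lists of matched expression in these libraries.

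The early suspension was mostly FAP-like cells and neutrophil-like cells, and the later one was mostly neutrophil-like cells. Monocyte-like cells held a somewhat larger share at 9 h, and cells resembling resident macrophages, tissue cells that sit in the uninjured muscle, held a smaller one. Lymphocytes were few at 9 h. Neutrophil-like cells were 33.3% of kept cells at 2 h (1633 cells, exact Clopper-Pearson interval 32.0 to 34.7%) and 53.1% at 9 h (4328 cells, 52.0 to 54.2%), a share 1.59 times as high. FAP-like cells were 40.9% at 2 h (2005 cells, 39.5 to 42.3%) and 19.6% at 9 h (1599 cells, 18.8 to 20.5%), a share ratio of 0.480. Monocyte-like cells were 3.47% at 2 h (170 cells) and 4.44% at 9 h (362 cells, 4.01 to 4.91%), a share ratio of 1.28. Resident macrophage-like cells were 6.39% at 2 h (313 cells, 5.72 to 7.11%) and 2.92% at 9 h (238 cells, 2.57 to 3.31%), a share ratio of 0.457. Endothelial-like cells were 5.31% at 2 h (260 cells) and 5.81% at 9 h (473 cells). Dendritic-like cells were 2.86% and 1.36% of cells, T or NK-like cells 2.10% and 0.454%, and B-like cells 0.918% and 0.0491%. Satellite-like cells, the muscle stem cells, were 1.63% at 2 h and 0.847% at 9 h, and tenocyte-like cells were 1.88% and 0.601%. Because shares add up to a whole, the same cells were also counted over the cells that were not neutrophil-like (3267 at 2 h and 3819 at 9 h). There, monocyte-like cells were 5.20% at 2 h (4.47 to 6.02%) and 9.48% at 9 h, endothelial-like cells 7.96% and 12.4%, resident macrophage-like cells 9.58% and 6.23%, and FAP-like cells 61.4% and 41.9%.

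The FAP share hinged on 1 cluster that was nearly absent at 2 h. Cluster 7 held 15 cells at 2 h (0.306%) and 768 cells at 9 h (9.43%, 8.80 to 10.1%). It had every one of the 15 FAP markers and carried Pdgfra at 495 and Dcn at 12070 CPM, but none of those markers was among its 10 leading genes, which were Saa1, Cxcl14, Ptx3, Prg4, Fst, Il33, Serpina3n, Adamts5, Cxcl13 and Scn7a. Scn7a was on the glial marker list, so by the naming rule the cluster was left without a name. Scn7a was at 495 CPM in cluster 7, at 357 in FAP-like cluster 3 and at 51.6 in the glial-like cells. Counted as FAP-like, the cluster brought the FAP share to 41.2% at 2 h (2020 cells) and 29.1% at 9 h (2367 cells, 28.1 to 30.1%), a share ratio of 0.705. Over the cells that were not neutrophil-like, FAP-like cells with cluster 7 were 61.8% at 2 h and 62.0% at 9 h, so the smaller FAP share in that count rested on leaving the cluster out. The decision was settled after both sets of values had been seen, and the main FAP values are therefore given both ways below. FAP-like cells of the libraries also fell into different clusters: clusters 3 and 11 held 1376 and 619 of the 2 h cells, and clusters 6 and 10 held 859 and 674 of the 9 h cells. Neutrophil-like cells were split in the same manner, with 1557 of the 2 h cells in cluster 1 and 1460, 1025, 890 and 655 of the 9 h cells in clusters 2, 4, 5 and 9.

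**Figure D1:**
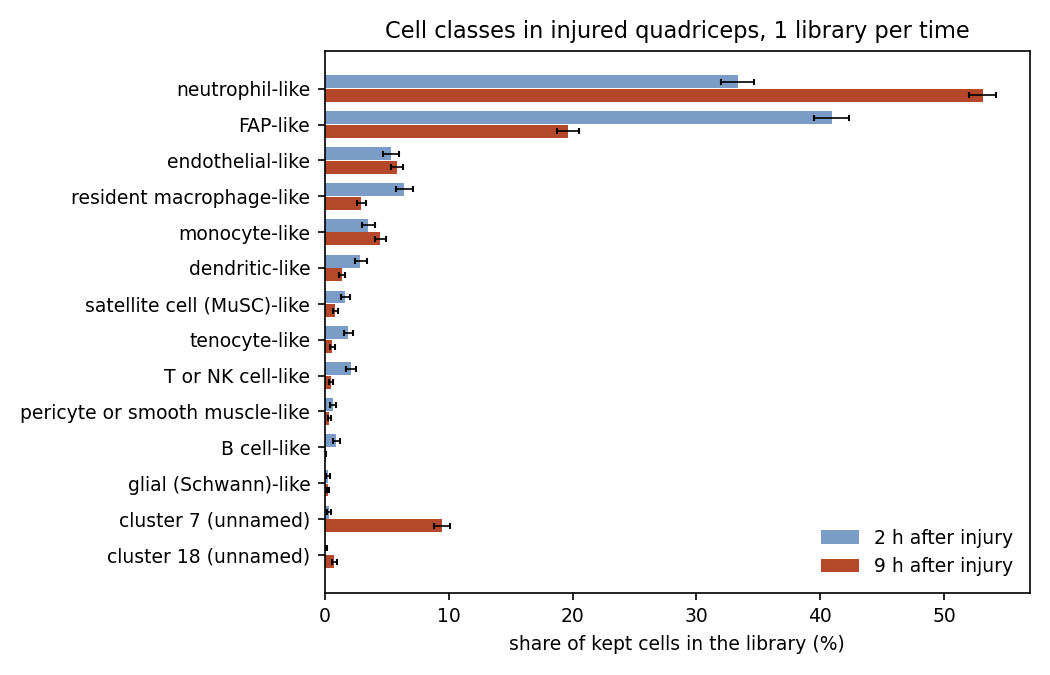
Share of kept cells (percent, linear axis) in each cell class and in the unnamed clusters 7 and 18, with 1 bar for the 2 h library and 1 for the 9 h library and exact 95% binomial intervals. FAP-like cells were 40.9% at 2 h and 19.6% at 9 h, and cluster 7 was 0.306% and 9.43%.

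The main question was which cells carried Ccl2. FAP-like cells held most of it at both times, and their level was far higher at 9 h. Resident macrophage-like cells carried Ccl2 too, at a level that was above that of FAP-like cells at 2 h, and monocyte-like cells at a level below it. At 9 h both were far below FAP-like cells. Ccl2 (ENSMUSG00000035385, mm10 chromosome 11, 82035571 to 82037453, plus strand) was at 656 CPM in FAP-like cells at 2 h (10664 UMIs, Poisson interval 644 to 669) and at 11837 at 9 h (160766 UMIs, 11779 to 11895), a ratio of 18.0 (17.7 to 18.4). FAP-like cells held 74.4% of all Ccl2 UMIs at 2 h (73.7 to 75.1%) and 85.7% at 9 h (85.5 to 85.8%). With cluster 7 the level was 656 at 2 h and 8877 at 9 h, a ratio of 13.5 (13.3 to 13.8), and the share of Ccl2 UMIs was 74.5% and 92.5%. Cluster 7 by itself was at 2141 CPM at 9 h (2104 to 2179). The median FAP-like cell had 0 Ccl2 UMIs at 2 h and 37 at 9 h, and the tenth of cells with the most Ccl2 held 86.8% of the UMIs at 2 h and 41.7% at 9 h. The intervals on summed UMIs leave out this spread between cells. Ccl2 was among the leading genes that set FAP-like clusters 6 and 10 apart, so its level was not compared among the FAP-like clusters. The 2 h cells lay mostly in clusters 3 and 11 and the 9 h cells in clusters 6 and 10. The ratio between the times is thus largely a ratio between these clusters.

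Resident macrophage-like cells had the highest Ccl2 level of the larger classes at 2 h, at 1025 CPM (983 to 1069), and were at 2634 at 9 h (2553 to 2717), 2.57 times as high (2.44 to 2.71). Monocyte-like cells were at 459 at 2 h and at 1820 at 9 h (1763 to 1878), 3.97 times as high (3.64 to 4.33). Taken as 1 group, monocyte-like and macrophage-like cells were at 812 at 2 h and at 2160 at 9 h (2113 to 2209), a ratio of 2.66 (2.55 to 2.78), and they held 19.4% of all Ccl2 UMIs at 2 h and 4.17% at 9 h. The 812 of this group at 2 h was 464, and so below FAP-like cells, at a clustering resolution of 0.5, where the resident macrophages got no name. Dendritic-like cells were at 135 and 533, but with each cell thinned to 1000 UMIs 10.1% of them had a Ccl2 UMI at 2 h and 6.54% at 9 h, and RNA of FAP-like cells at the share of Dcn found in them would bring more (1218 at 9 h), so no direction was read there. The same estimate gave 682 of the 2634 in resident macrophage-like cells and 64.9 of the 1820 in monocyte-like cells at 9 h. Endothelial-like cells were at 5.33 and 69.6. Pericyte-like or smooth muscle-like cells were at 497 and 2085, but 84 of their 112 UMIs at 2 h were in 1 cell. Tenocyte-like cells were at 545 and 570, and satellite-like cells at 17.1 and 18.9. Neutrophil-like cells, which served as a measure of free RNA although classes differed in how much they carried, were at 26.0 at 2 h and 65.9 at 9 h. B-like cells had none. Unnamed cluster 18, led by Postn and by endothelial genes, had 61 cells at 9 h and a level of 9229 there, with 2.02% of the Ccl2 UMIs. Glial-like cells at 9 h showed 8587 CPM, but 684 of their 688 UMIs were in 1 cell.

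**Figure D2:**
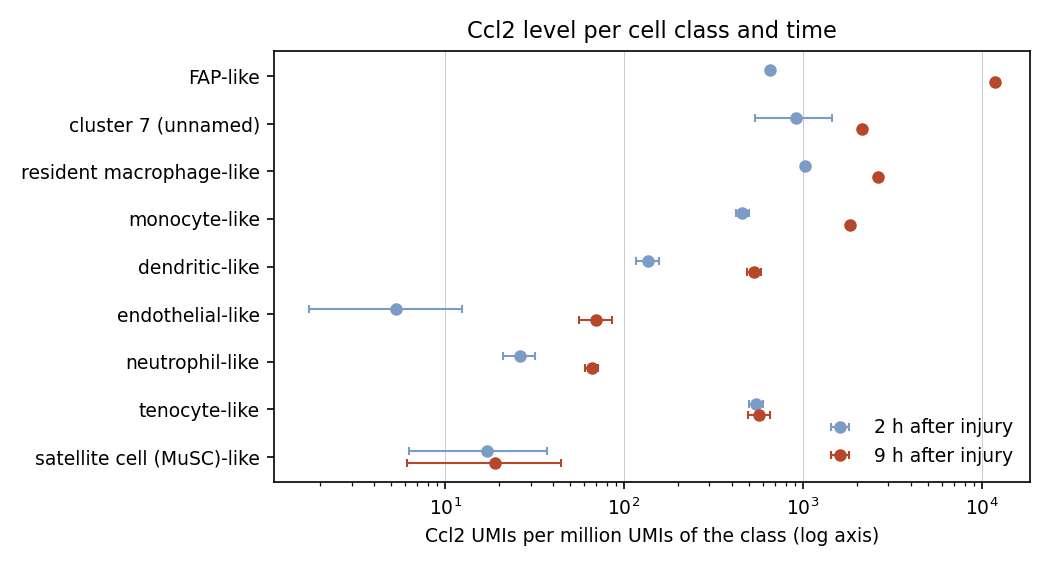
Ccl2 level in CPM (log axis) per cell class, with 1 point for the 2 h library and 1 for the 9 h library and 95% Poisson intervals that cover counting error only. FAP-like cells were at 656 and 11837, resident macrophage-like cells at 1025 and 2634, and neutrophil-like cells at 26.0 and 65.9.

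More FAP-like cells had any Ccl2 molecule at 9 h, also at equal depth. With each cell thinned to 1000 UMIs, 15.6% of 1989 FAP-like cells had a Ccl2 UMI at 2 h (14.1 to 17.3%) and 72.5% of 1559 at 9 h (70.3 to 74.7%). Shallower cells left out were 16 and 40, and the median depths before thinning were 8044 and 8619 UMIs. Without thinning the shares were 28.2% and 82.2%. With cluster 7, the thinned shares were 15.7% and 60.3%. Neutrophil-like cells, as background, were at 1.17% at 2 h (0.695 to 1.84%) and 5.70% at 9 h, with 2.08% and 9.08% unthinned, 94 and 325 cells left out and median depths of 2041 and 1715. Of 44 B-like cells at 2 h, 0 had a Ccl2 UMI after thinning, so the share of such cells has an upper limit of 8.04% by the exact interval and 6.82% by a floor of 3 cells. T or NK-like cells were at 1.98% and 10.8%. Resident macrophage-like cells were at 35.3% at 2 h (29.9 to 40.9%) and 55.0% at 9 h (48.3 to 61.5%), and unthinned at 64.2% and 74.8%, with 7 cells left out at each time. Neutrophil-like cells are a low background for them, with Dcn at 63.7 CPM at 9 h against 364. Carried-over RNA of FAP-like cells would bring 36.9 of their 1025 CPM of Ccl2 at 2 h and 682 of 2634 at 9 h. It could raise their share of cells with a UMI, so the higher share at 9 h is not firm. Monocyte-like cells were at 28.0% (21.3 to 35.4%) and 43.9% (38.6 to 49.2%), and unthinned at 63.5% and 71.3%. Endothelial-like cells, at 0.415% and 3.70%, were not above the neutrophil-like background.

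Other ligands for the monocyte receptor CCR2 and for neutrophils were measured beside Ccl2. Ccl7, the neighbouring gene and a second CCR2 ligand, also lay mainly in FAP-like cells. Neutrophil-attracting CXC chemokines divided between FAP-like and neutrophil-like cells, gene by gene, and the receptor gene Ccr2 had its highest level in monocyte-like cells. Ccl7 (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525, plus strand) was at 970 CPM in FAP-like cells at 2 h and at 4466 at 9 h, a ratio of 4.60 (4.52 to 4.69), or 3.69 with cluster 7. FAP-like cells held 83.5% of Ccl7 UMIs at 2 h and 78.8% at 9 h, or 90.9% at 9 h with cluster 7. Ccl7 in monocyte-like cells was at 42.8 and 616, 14.4 times as high at 9 h, and in resident macrophage-like cells at 1042 and 2335, 2.24 times as high (2.12 to 2.36). Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557, plus strand) was at 511 in monocyte-like cells at 2 h and at 646 at 9 h, and this class held 39.6% of Ccr2 UMIs at 2 h and 67.5% at 9 h, against 32.1% and 20.1% in resident macrophage-like and 18.5% and 7.92% in dendritic-like cells. Ccr2 in resident macrophage-like cells was at 250 and 268, a ratio whose interval held 1 (0.940 to 1.22), and in FAP-like cells it was at 3.61 CPM at 9 h. Of all Cxcl5 UMIs, FAP-like cells held 94.8% at 2 h and 88.4% at 9 h, and of all Cxcl1 UMIs 93.8% and 83.9%. With cluster 7 these shares at 9 h were 96.5% and 93.6%, so the lower shares at 9 h rested mostly on leaving the cluster out. Cxcl2 and Cxcl3 were mostly in neutrophil-like cells, where Cxcl2 was at 23224 and 55090 and Cxcl3 at 1647 and 7349, and FAP-like cells held 10.2% of Cxcl2 UMIs and 28.4% of Cxcl3 UMIs at 9 h. FAP-like cells also held 56.3% of the UMIs of the macrophage growth factor Csf1 at 9 h and 80.9% of those of Il6, or 65.4% and 93.1% with cluster 7. The neutrophil receptor Cxcr2 was at 709 at 2 h and 744 at 9 h in neutrophil-like cells.

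FAP-like cells at 9 h had far more chemokine, cytokine and ribosome-building transcripts than at 2 h, and far fewer transcripts of collagens, of immediate early genes, of heat shock genes and of interferon-response genes. Among the matrix genes, those that build fibrils were lower at 9 h, and several that remodel the matrix were higher. Surface and secreted markers of resting FAP subsets were mostly lower. The highest ratio of the named genes was that of Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624, plus strand), at 50.7 CPM at 2 h and 15316 at 9 h, 302 times as high (282 to 324). Hmga2, a chromatin gene of growing mesenchyme, was at 0.492 and 143 (ratio 290.0, 147 to 673), and Il1rl1, the receptor of interleukin-33, was at 5.60 and 664 (ratio 119, 96.5 to 147). The ligand Il33 itself was at 2124 at 9 h, 8.31 times as high. Cxcl3 was 96.1 times as high at 9 h (86.7 to 107) and Cxcl2 was at 382 and 4587, but neutrophil-like cells carried more of both. Their RNA, at the share given by S100a8, would bring 15.5 of the 22.6 CPM of Cxcl3 at 2 h and 218 of the 382 of Cxcl2. At 9 h it would bring 153 of the 2169 of Cxcl3 and 1150 of the 4587 of Cxcl2. The size of either ratio is therefore not firm. Tnc, an injury matrix protein, was at 4.92 and 394 (ratio 80.0; its log2 ratio of 4.76 was 3.27 at a clustering resolution of 2), and the metallothionein Mt4 at 2.03 and 127 (ratio 62.6, 44.4 to 91.2). Angptl4 was 17.6 times as high, Adam12 13.3 times and Igfbp3 10.2 times. Cxcl5, Il33, Ccl2, Tnc, Il1rl1 and Mt4 were among the leading genes of the 9 h clusters, so they are not independent of the clustering. The same holds for Ccl7, Cxcl1, Mmp3 and Ptx3.

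Of the named genes lower at 9 h, Gas1 was at 8.10 CPM at 9 h, 40.6-fold lower than at 2 h (33.6 to 49.4), and Tppp3, at 364 CPM at 2 h, was 52.0-fold lower (42.4 to 64.3). Abca8a was at 883 at 2 h and 23.7 at 9 h (37.3-fold lower, 33.4 to 41.7), and Col15a1 at 715 and 21.4 (33.5-fold lower). Angptl1 was 24.6-fold lower, Eln 23.9-fold, Dpysl2 17.3-fold and Creb5 14.3-fold. Col3a1, a main fibril collagen, was at 6603 at 2 h and 636 at 9 h, 10.4-fold lower, and Col5a1 was 15.3-fold lower. Cd34, a surface protein used to sort FAPs, was at 776 and 72.7, 10.7-fold lower (10.0 to 11.4). The interferon-induced gene Iigp1 was at 419 at 2 h and 17.3-fold lower at 9 h (15.5 to 19.4), a log2 ratio of -3.65. Counting cluster 7 as FAP-like brought the log2 ratio of Iigp1 to -2.04, that of Col3a1 from -3.35 to -2.71 and that of Abca8a from -4.73 to -3.99. Abca8a, Col15a1, Gas1, Angptl1 and Col3a1 were among the leading genes of FAP-like cluster 3, which held mostly 2 h cells. These genes are therefore not independent of the clustering either.

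By list, all 4 measured CXC chemokines were higher in FAP-like cells at 9 h (median log2 ratio 4.81, percentile 100), as were 7 of the 8 CC chemokines (median 1.70, percentile 100), Ccl11 being the exception at 3.09-fold lower (3.02 to 3.16). Cxcl1 was at 1394 and 6876, 4.93 times as high. The CXC median was set by Cxcl2 and Cxcl3, much of whose 2 h level could be carried-over neutrophil RNA, so its size is not firm. Ccl3 and Ccl4 were higher too, but at 247 and 340 at 9 h they were far under the 10386 and 12129 of neutrophil-like cells, whose RNA at the share given by S100a8 would bring 217 and 253. Without them the list had 5 of 6 higher (median 0.80). Other chemokines were mostly lower (5 of 7, median -1.12, percentile 0.28), with Cxcl10 6.73-fold lower, Cxcl9 at 68.8 and 13.8, Cxcl13 4.18 times and Cxcl12 1.94 times as high. Cxcl14 was at 2631 at 2 h and 1209 at 9 h, but with cluster 7, which it helped to define, at 2629 and 3346, and the median of that list then was -0.05. At a clustering resolution of 2 the medians of CXC, CC and other chemokines were 2.95, 1.06 and -0.04, and without a filter on low counts 3.55, 0.85 and -0.26. Of 13 cytokines 12 were higher (median 1.13, percentile 100), among them Csf1 (229 and 1007), Lif (4.78 times), Csf2 (16.6 times) and Il6 (1.84 times). Il1b, Il1rn and Tnf were near the level of carried-over neutrophil RNA, and without them 9 of 10 were higher. All 11 measured genes of ribosome biogenesis were higher (percentile 100), with Npm1 5.75 times and Ncl 5.73 times as high. Glycolysis and hypoxia genes were higher in 10 of 16 (median 0.60, percentile 99.2), Ldha by 3.04 times and Hif1a by 2.35 times. In the growth factor list, 8 of 15 were higher, among them Ccn2 (4.24 times) and Inhba (5.06 times), while Igf1 was 2.20-fold and Wnt5a 6.39-fold lower.

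Structural matrix genes were lower at 9 h in 17 of 18 (median -2.33, percentile 0), Mfap5 being the exception at 1.54 times as high; Col1a1 was at 2187 and 274, 7.97-fold lower, and Dcn 2.67-fold lower. Matrix remodelling genes went both ways (10 of 22 higher): Mmp3 was 7.83 times as high, Timp1 6.36 times and Ptx3 4.67 times, while Tnfaip6 was 8.40-fold lower and Mmp2 3.37-fold lower. Immediate early genes were lower in 19 of 21 (median -1.58, percentile 0), with Egr1 at 3111 and 461 (6.75-fold lower), Fos 7.50-fold lower and Atf3 10.1-fold lower, and with Fosl1 (4.49 times as high) and Ier3 (2.84 times) as exceptions. Heat shock genes were lower in 9 of 11 (median -1.36, percentile 0.1), Hspa1b being at 4888 and 1242 and Dnajb1 7.19-fold lower, while the mitochondrial chaperone genes Hspd1 and Hspe1 were higher. All 12 measured interferon-response genes were lower (median -1.58, percentile 0), such as Ifit1, which was 13.1-fold lower (10.9 to 15.8), and Isg15, 5.65-fold lower. FAP subset genes were lower in 13 of 14 (median -1.97, percentile 0), including Smoc2 (3.49-fold lower) and Pi16 (2.08-fold lower). Targets of NF-kB were higher in 9 of 14 (median 0.41, percentile 92.8), Sod2 by 4.19 times and Nfkbia by 2.06 times. Genes of the unfolded protein response were lower in 8 of 11 (median -0.59), among them Hspa5 (1.51-fold lower), with Asns 4.95 times as high. Mitochondrially encoded genes were lower in 12 of 13 (median -0.55, percentile 2.18). With cluster 7 counted, the medians were 4.39 for CXC chemokines, 1.43 for CC chemokines, 0.90 for cytokines, 1.47 for ribosome biogenesis, -1.96 for structural matrix, -1.44 for heat shock and -1.49 for interferon-response genes.

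**Figure D3:**
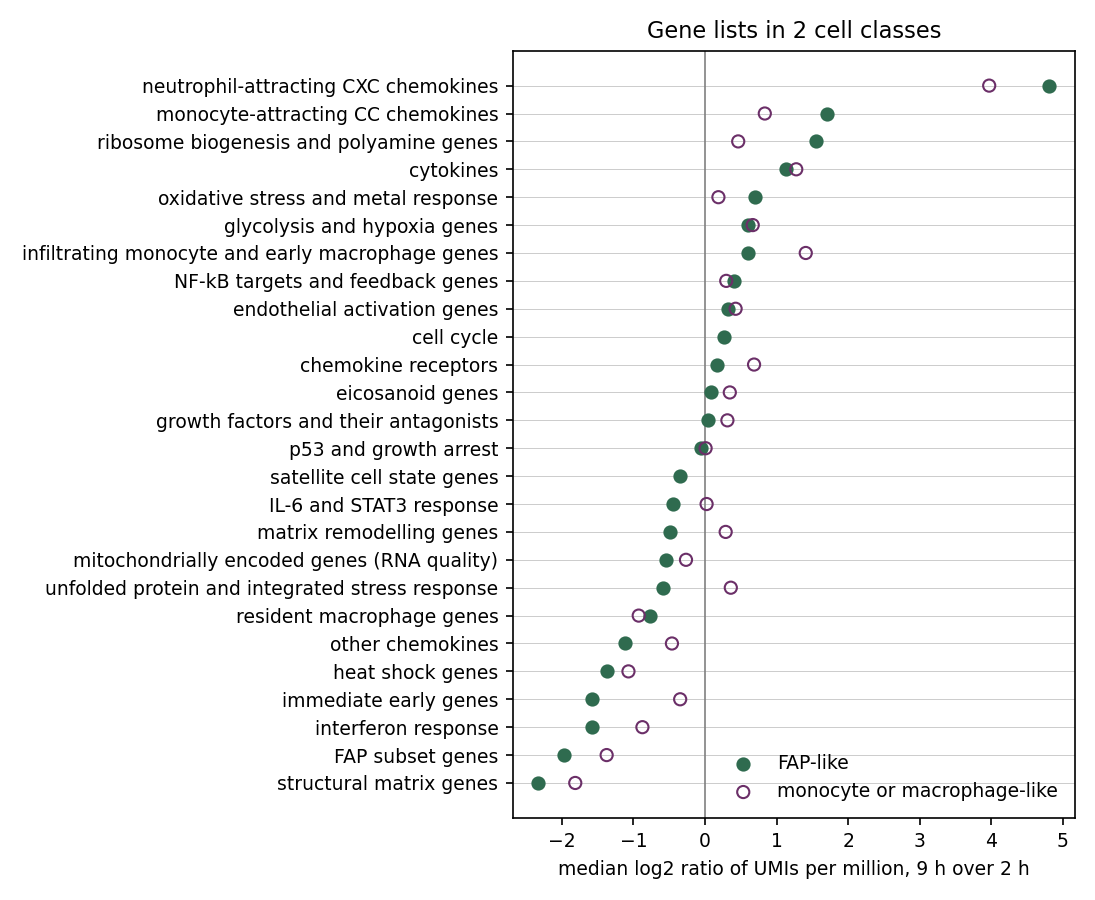
Median log2 ratio of 9 h to 2 h (horizontal axis) for each of the 26 gene lists, in FAP-like cells (filled points) and in monocyte-like and macrophage-like cells together (open circles). Cell cycle and satellite cell state genes have no open circle, since 2 genes of each were measured in that group. In FAP-like cells the medians ran from -2.33 for structural matrix genes to 4.81 for CXC chemokines.

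FAPs comprise an adventitial subset that carries Pi16 and a parenchymal subset that carries Cxcl14. Ccl2 was higher at 9 h in each group of FAP-like cells set by UMIs of these genes, groups that need not be the subsets themselves. Among FAP-like cells with a Pi16 UMI it was at 631 at 2 h and 8840 at 9 h (ratio 14.0, 13.6 to 14.4). Among those with a Cxcl14 UMI and no Pi16 UMI it was at 671 and 14514 (ratio 21.6), and among those with neither at 748 and 13551 (ratio 18.1). Cxcl5 was also higher in each of the 3 groups, by 206 times with Pi16, by 307 times with Cxcl14 alone and by 405 times with neither. With cluster 7, the Ccl2 ratios in the same order were 11.7, 14.2 and 15.8, the Ccl2 level of cells with Cxcl14 alone was 9523 at 9 h, and the Cxcl5 ratios were 174, 200 and 379.

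Monocyte-like and macrophage-like cells together carried more transcripts of infiltrating monocytes and early macrophages at 9 h and fewer of resident ones. CC and CXC chemokines, cytokines and genes of glycolysis were higher, and interferon-response and heat shock genes were lower. The make-up of the group differed as well, with 170 monocyte-like cells among its 483 cells at 2 h and 362 among its 600 at 9 h. Arg1, an arginase, had 2 UMIs at 2 h and a level of 278 at 9 h (ratio 476, 131 to 3936). Spp1, osteopontin, was at 79.8 and 1103, 13.8 times as high (12.2 to 15.7), and was at 154 and 1752 in monocyte-like cells and 35.1 and 202 in resident macrophage-like cells. Ppbp, which is also a platelet gene, was 34.8 times as high (27.7 to 44.2), the activin gene Inhba 28.0 times (19.8 to 40.9), Saa3 14.7 times and Hilpda, a hypoxia-induced lipid droplet gene, 11.4 times. Cxcl3 was 16.7 times as high, Mmp8 7.07 times, Ptgs2 6.43 times, Slpi 5.87 times and Timp1 8.96 times; neutrophil-like cells at 9 h carried Cxcl3, Mmp8, Ptgs2, Slpi and Spp1 as well. Of the genes lower at 9 h, Selenop was at 1375 and 235 (5.86-fold lower, 5.44 to 6.31), Fcrls was 8.09-fold lower, Cbr2 5.22-fold, Gas6 9.45-fold and Igfbp4 17.8-fold (12.9 to 25.3). Mucl1 was 17.3-fold lower, Dpysl2 10.2-fold, Ckb 9.02-fold, Fxyd2 6.62-fold and Fcgrt 5.21-fold. Tppp3 was at 217 and 13.8 in this group. Ccl17 was 51.4 times as high (29.2 to 100.04), but it led the dendritic-like cluster, and its log2 ratio of 3.82 was 0.41 with at least 500 genes and 1000 UMIs per cell. Igfbp4, Gas6, Dpysl2, Selenop, Fcgrt, Ckb and Tppp3 were lower in FAP-like cells too. At 2 h their levels in this group were 5.20 times (Igfbp4) to 65.9 times (Selenop) what RNA of FAP-like cells would bring at the share given by Dcn (3.75% of the FAP-like level), so such RNA does not account for them there. At 9 h Igfbp4 was at 10.8, with 10.2 carried over, so its ratio has no measured size. Structural matrix genes were also lower in 13 of 13 (median -1.81, percentile 0), but these were at the level of carried-over RNA: Col3a1 was at 292 at 2 h, where such RNA would bring 247, and over the 12 genes other than Dcn the median of observed over carried-over level was 0.997 at 2 h and 0.806 at 9 h. The lower matrix genes are therefore not read as a change of these cells. Ccl8, a chemokine of resident macrophages, was at 350 and 38.2 in resident macrophage-like cells.

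In the lists, 14 of 17 genes of infiltrating monocytes and early macrophages were higher in this group at 9 h (median 1.41, percentile 100). Thbs1 was at 1665 and 6723, 4.04 times as high (3.92 to 4.16), Il1b at 437 and 1871, 4.28 times (4.04 to 4.53), and Vcan was 3.52 times as high, while Ly6c2 and Plac8, markers of blood monocytes, were 2.05-fold and 2.20-fold lower. Resident macrophage genes were lower in 9 of 11 (median -0.93, percentile 0), with C1qa 2.20-fold, Folr2 3.30-fold and Lyve1 2.99-fold lower, and with Pf4 1.78 times and F13a1 1.27 times as high. Of the CC chemokines 7 of 9 were higher (median 0.84, percentile 100), and other chemokines were lower in 4 of 6 (median -0.46, percentile 3.09). All 5 CXC chemokines (median 3.97), of which Cxcl5, at 423 with 418 carried over from FAP-like cells, is not read as their own, and all 11 cytokines (median 1.27, percentile 100) were higher, including Il10 (2.69 times) and Tnf (2.18 times). Glycolysis and hypoxia genes were higher in 11 of 15 (median 0.67, percentile 100), with Vegfa 3.54 times and Pkm 2.47 times as high. The chemokine receptor gene Cx3cr1 was 4.39-fold lower. All 11 heat shock genes (median -1.07) and all 9 interferon-response genes (median -0.87) were lower, with Hspb1 3.89-fold, Irf7 3.68-fold and Bst2 3.22-fold lower. Genes of the unfolded protein response were higher in 10 of 10 (median 0.36, percentile 99.6), Creld2 by 4.01 times and Manf by 2.61 times.

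Taken apart, the classes differed. In resident macrophage-like cells, genes of infiltrating monocytes were higher in 12 of 13 (median 1.46, percentile 100) and resident macrophage genes were lower in 8 of 11 (median -0.40, percentile 0.47), with Selenop 4.77-fold and Cbr2 3.70-fold lower and with Pf4 2.43 times and Cd163 1.40 times as high. The same cells had 11 of 11 heat shock genes lower (median -1.09). Ppbp was 48.3 times as high in them (38.5 to 61.4) and Abca9 11.2-fold lower. Ppbp was on the platelet marker list and led their cluster, and Pf4 is a platelet gene as well, so RNA of platelets stays open for both. Ccl17 was 75.9 times as high (43.1 to 148), but with at least 500 genes and 1000 UMIs per cell its log2 ratio of 4.80 was 0.99. In monocyte-like cells Ly6c2 and Plac8, markers of blood monocytes, were 3.16-fold and 3.41-fold lower, but Chil3 was at 2231 and 2760 and F10 at 278 and 486. The same cells had Spp1 11.4 times, Inhba 50.1 times (27.1 to 105) and Ptgs2 7.93 times as high. Arg1 had no UMI in monocyte-like cells at 2 h and 304 at 9 h, at least 61.8-fold higher against a floor of 3 counts. Genes of the resident macrophage list were higher in 5 of 6 in monocyte-like cells (median 0.97, percentile 99.8), Pf4 by 10.7 times (8.18 to 14.1). Heat shock genes were higher in 10 of 11 (median 0.36, percentile 99.6), Hspa1b being at 1900 and 3085, and genes of the unfolded protein response were higher in 7 of 9 (median 1.13, or 0.45 without a filter on low counts), with Creld2 5.99 times and Manf 4.63 times as high. Interferon-response genes were lower in 7 of 8 (median -1.58, percentile 0, or -0.46 without that filter), with Irf7 5.20-fold lower and Rsad2 3.13 times as high. Itga4, an integrin of circulating monocytes, was 5.85-fold lower.

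Neutrophil-like cells at 9 h carried more cytokine and chemokine transcripts and fewer interferon-response transcripts than those at 2 h. Their NF-kB feedback genes were higher as well. Each time had most of these cells in clusters of its own, so the contrast was largely that of cluster 1 against clusters 2, 4, 5 and 9. F10 was 39.9 times as high at 9 h (24.8 to 68.7), Chil3 was at 8.78 and 264, and Fcgr2b was 21.3 times, Fmnl2 20.4 times and the neutrophil surface gene Cd177 16.1 times (12.9 to 20.4). Chil3 and F10 were also carried by monocyte-like cells, at 2760 and 486 CPM at 9 h. Pmvk was 14.0-fold lower (11.7 to 16.9), Scnn1a 9.46-fold, Rsad2 8.26-fold (7.05 to 9.70) and Ifi27l2a 7.86-fold (7.10 to 8.72). Interferon-response genes were lower in 7 of 8 (median -1.81, percentile 0), Isg15 by 4.48-fold. All 9 cytokines (median 1.63), all 6 CC chemokines (median 1.35) and all 4 CXC chemokines (median 2.08) were higher, with Ccl4 8.92 times, Il1rn 3.56 times and Cxcl2 2.37 times as high. Without a filter on low counts, the median was -1.05 for interferon-response genes and 0.25 for cytokines. NF-kB targets were higher in 11 of 13 (median 0.82, percentile 100), Nfkbia by 3.37 times. Heat shock genes went both ways (3 of 9 higher, median -0.07, percentile 59.0).

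Endothelial-like cells showed the lowest interferon-response median of the classes compared and had more of some genes of activated endothelium at 9 h. All 10 measured interferon-response genes were lower (median -2.15, percentile 0), Ifit2 by 43.3-fold and Ifit1 by 22.4-fold (15.7 to 32.8). The interferon-induced GTPase genes Iigp1 and Irgm1 were 23.3-fold (18.1 to 30.4) and 26.8-fold (14.7 to 54.5) lower, and Ifi203 was 10.8-fold lower, a log2 ratio of -3.09 that was -1.45 with a mitochondrial limit of 10%. Pgf, placental growth factor, was 22.8 times as high (15.5 to 34.7) and AA467197 18.5 times (13.9 to 25.1). Ccl3 and Ccl4 were 11.7 and 17.3 times as high, but neutrophil-like cells at 9 h were at 10386 and 12129 for them, so free RNA stays open. Neutrophil RNA at the share given by S100a8 would bring 935 of the 1413 CPM of Ccl3, 1092 of the 1201 of Ccl4 and 87.6 of the 380 of Lrg1, so it does not account for Lrg1. Of 6 endothelial activation genes 4 were higher (median 0.76, percentile 99.9, or 0.01 without a filter on low counts), Ctla2a being at 1610 and 8360, Angpt2 3.19 times and Lrg1 2.55 times as high, while Selp was 3.25-fold and Plvap 4.61-fold lower. Ribosome biogenesis genes were higher in 7 of 8 (median 1.42, percentile 100), and all 11 heat shock genes were lower (median -1.02, percentile 0). The chemokine Cxcl12 was at 838 and 244, 3.44-fold lower (3.01 to 3.93).

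Dendritic-like cells at 9 h carried more Ccr7, Ccl17 and Ccl22, though such genes also lead the cluster, and more NF-kB transcripts. Genes of FAP-like cells were higher in them as well, with Dcn at 48.1 and 650, 13.5 times as high, so RNA of FAP-like cells or doublets stay open for the genes that FAP-like cells carry. Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 81.9 and 1616, 19.7 times as high (16.2 to 24.2), and the chemokines Ccl17 and Ccl22 were at 3848 and 2414 at 9 h, 31.2 and 26.3 times as high. Fabp5 was 34.2 times as high (28.4 to 41.7), and Fabp4 39.2 times, though endothelial-like cells carried Fabp4 at 12215. Icam1 was 3.29 times and Nfkb1 2.43 times as high, within 11 of 12 higher NF-kB genes (median 0.87, percentile 100). Cd163 was 17.4-fold lower (7.80 to 48.1), Lyz2 4.84-fold and Itgb7 5.97-fold. With at least 500 genes and 1000 UMIs per cell, the log2 ratios moved from 4.94 to 3.98 for Fabp5, from 4.52 to 2.63 for Fabp4, from -2.93 to -0.87 for Cd163 and from -2.24 to -0.91 for Lyz2, and the median of structural matrix genes turned from 0.78 to -1.60. The matrix median was 2.15 with a mitochondrial limit of 10% and 0.18 as a mean over cells. Tppp3, which had 3 UMIs at 9 h, was 42.3-fold lower (14.3 to 207). Interferon-response genes went both ways here (2 of 4 higher, median -0.29, percentile 16.0), as did heat shock genes (4 of 11 higher, median -0.21, percentile 31.9). Satellite-like, tenocyte-like, pericyte-like, lymphoid and glial-like cells had fewer than 100 cells in at least 1 library, and their genes were not compared between the times.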

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

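The tests of free RNA, of depth and of a library difference for Ccl2, and the test of handling for the heat shock genes, were chosen only after the result was seen.

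Gene lists drew attention where their median log2 ratio, against matched random lists, lay on opposite sides of 0 in 2 classes. With 1 library per time, none of these differences between classes was tested. Heat shock genes were higher at 9 h in monocyte-like cells (10 of 11, median 0.36) and lower in FAP-like cells (9 of 11, median -1.36), medians that lay 1.73 apart. The genes under other chemokines were higher in dendritic-like cells (4 of 5, median 2.45) and lower in FAP-like cells (5 of 7, median -1.12), 3.56 apart, but neither side is firm. The dendritic-like median was that of Cxcl14, which lay at the level of RNA carried over from FAP-like cells (97.8 CPM at 9 h against 124). That median was 0.79 without a count filter, 1.42 as a mean over cells and 1.49 with 500 genes and 1000 UMIs. It was higher, at 3.46, with a mitochondrial limit of 10% and at 3.20 with a pseudocount of 1 CPM. The FAP-like value was -0.05 when cluster 7 was counted as FAP-like. Resident macrophage genes were higher in monocyte-like cells (5 of 6, median 0.97) and lower in FAP-like cells (5 of 7, median -0.77), 1.74 apart. RNA carried over from resident macrophage-like cells into FAP-like cells was not estimated, and the share of the former was lower at 9 h (6.39 and 2.92%). Such RNA stays open for the FAP-like side. The FAP-like median turned to 0.73 with a mitochondrial limit of 10% and to 0.72 with at least 500 genes and 1000 UMIs per cell, for reasons that were not tested.

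Ccl2 was 18.0 times as high in FAP-like cells at 9 h, or 13.5 times with cluster 7. Free RNA spread evenly would put Ccl2 at about the same level in every cell, yet neutrophil-like cells at 9 h had 0.557% of the FAP-like level. By Dcn, however, such RNA was not even across classes. At 9 h Dcn was at 63.7 CPM in neutrophil-like, 225 in endothelial-like, 364 in resident macrophage-like and 650 in dendritic-like cells. Dendritic-like cells, with the most Dcn of these, had Ccl2 at 533 against 11837 in FAP-like cells. Deeper cells at 9 h were argued against by the share of FAP-like cells with a Ccl2 UMI, which was 4.64 times as high at 9 h when each cell was thinned to 1000 UMIs. Another mix of cells with and without UMIs of Pi16 and Cxcl14 was argued against by the ratio within these strata. The lowest ratio was 14.0, or 11.7 with cluster 7. The levels of both genes in FAP-like cells themselves differed between the times, so a stratum may hold other cells at each time. The strata thus cannot settle whether the mix of the adventitial and parenchymal subsets changed. A changed mix of subsets that these genes do not mark was not tested and stays open. Also open is a difference between animals or libraries other than time. With 1 library per time, it cannot be told apart from the time after injury, which remains an untested explanation.

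FAP-like cells of the libraries had few neighbours in common. In equal numbers of cells at equal depth, 3.94% of the nearest neighbours of FAP-like cells came from the other library (1.87 to 5.10% over 10 draws), against 21.2% in dendritic-like, 18.3% in resident macrophage-like and 16.5% in monocyte-like cells, with endothelial-like and neutrophil-like cells in between. A difference between the libraries that acts on all cells alike would not alone give a dendritic-like share 5.37 times the FAP-like share. In every class compared, though, most neighbours came from the same library. A shared difference with a further difference in FAP-like cells is therefore not excluded. The FAP-like cells here leave out cluster 7. The chemokine and cytokine genes alone did not account for the split, since without them the FAP-like share was 0.994 times the share with them. A response of FAPs to the injury between the times may be behind the split, as may a library difference that acts on FAP-like cells in particular.

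Heat shock genes were lower at 9 h in FAP-like (median -1.36), resident macrophage-like (-1.09) and endothelial-like cells (-1.02). Thawing or dissociation that differed between the libraries and acted on all cells alike would not alone give the monocyte-like median above 0 (0.36). That value had been seen before the test was chosen, and a monocyte-like rise on top of a shared shift would also give it. It therefore cannot exclude shared handling. Immediate early genes had medians below 0 in each class compared: FAP-like (-1.58), endothelial-like (-0.85), resident macrophage-like (-0.40), dendritic-like (-0.32), monocyte-like (-0.30) and neutrophil-like (-0.29, percentile 8.79). Free RNA from FAP-like cells was argued against as the source in endothelial-like cells: Hspa1b there at 2 h, at 8037 CPM, was 86.0 times the 93.4 CPM that free RNA carrying their Dcn would bring. Handling that acted on some cell types more than on others was not tested, and neither was a stress response to the injury itself. Both remain open, as does handling shared by all cells.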

How the results depend on the processing

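Counting cluster 7 as FAP-like was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each time had 1 library. The cause of the moves below was not tested.

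Under the alternatives, the values set to answer the comparisons stayed within their counting intervals in 58 cases and moved beyond them in 53, with no change of direction in the ratios. A reading between these values did turn: the FAP-like share of cells that were not neutrophil-like was lower at 9 h (61.4 and 41.9%) but level with cluster 7 (61.8 and 62.0%). At resolution 0.5 the value for monocyte-like and macrophage-like cells was below that of FAP-like cells for Ccl2 at 2 h. The resident macrophages got no name in that run, so the cells compared were not the same. The neutrophil-like and monocyte-like share ratios, the FAP-like Ccl2 level at 2 h and the endothelial-like interferon-response median stayed within their counting intervals in each run. Many of the moves were in FAP-like values, and most runs that changed the cells or the clustering gave values near those with cluster 7 counted as FAP-like: share ratio 0.705, Ccl2 at 8877 CPM at 9 h, 92.5% of Ccl2 UMIs at 9 h and a Ccl2 log2 ratio of 3.74.

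In the order FAP-like share ratio, FAP-like Ccl2 at 9 h (CPM) and FAP-like part of all Ccl2 UMIs at 9 h, the values were 0.716, 8962 and 93.1% with a mitochondrial limit of 10%, 0.602, 10488 and 93.4% without a limit, 0.534, 11513 and 88.9% with at least 500 genes and 1000 UMIs, 0.712, 9103 and 95.2% without the highest doublet scores, 0.712, 8905 and 92.7% at resolution 0.5, 0.678, 8823 and 89.8% at resolution 2, and 0.697, 8999 and 92.3% with each library clustered alone. The FAP-like part of Ccl2 UMIs at 2 h was 73.1% without a mitochondrial limit and with libraries clustered alone, 73.5% at resolution 0.5 and 76.2% at resolution 2. The FAP-like Ccl2 log2 ratio was 3.75 with the limit of 10%, 4.10 with 500 genes and 1000 UMIs, 3.73 at resolution 2, 4.25 with TMM and 4.26 with totals that leave out mitochondrial, ribosomal protein, haemoglobin and free RNA genes. The share of FAP-like cells with a Ccl2 UMI was 21.2% and 77.2% at 2000 UMIs and 28.2% and 82.2% unthinned.

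For monocyte-like and macrophage-like cells together, Ccl2 at 2 h was 771 CPM with the limit of 10%, 765 without a limit, 854 with libraries clustered alone and 464 at resolution 0.5, where the resident macrophages got no name; at 9 h it was 2269 with 500 genes and 1000 UMIs, 2076 without the highest doublet scores and 2440 at resolution 0.5. Their Ccl2 log2 ratio was 1.49 with the limit of 10%, 1.47 with 500 genes and 1000 UMIs, 1.55 with TMM and 1.08 as a mean over cells. The resident macrophage-like share ratio was 0.591 with libraries clustered alone. The neutrophil-like interferon-response median was -1.94 with the reduced totals, -2.25 with a pseudocount of 1 and -1.05 without a count filter.

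Of the named genes and lists, 1201 values stayed, 484 moved and 9 turned direction. Without a count filter, other chemokines in endothelial-like cells came to 0.0043, and growth factors and endothelial activation genes in monocyte-like and macrophage-like cells to -0.0225 and -0.0416. With the limit of 10%, resident macrophage genes in FAP-like cells came to 0.73 and matrix remodelling genes in monocyte-like and macrophage-like cells to -0.58. With 500 genes and 1000 UMIs, resident macrophage genes in FAP-like cells came to 0.72, and structural matrix, matrix remodelling and FAP subset genes in dendritic-like cells to -1.60, -0.23 and -1.20.

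TMM scaling shifted the median log2 ratio of all measured genes by 0.20 in monocyte-like, 0.12 in monocyte-like and macrophage-like together, 0.10 in neutrophil-like and -0.12 in dendritic-like cells. Depth limits the classes with under 100 cells in a library, whose genes were not compared, and Ccl2 in B-like cells, of which 4 were kept at 9 h.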

Other observations

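The tests of gene neighbourhoods below were written before their values were computed, but their genes were picked after the differences between the times had been seen.

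Krtdap, Dmkn and Sbsn are genes of the skin barrier that lie within 39627 bp of chromosome 7 (30751471 to 30791097). All were higher in FAP-like cells at 9 h, and all were among the leading genes of cluster 6, which held mostly 9 h cells. Krtdap was at 44.2 and 275 CPM, 6.22 times as high (5.74 to 6.75), Dmkn 3.06 times (2.88 to 3.25) and Sbsn 1.78 times (1.69 to 1.88). Krtdap UMIs were found in 14.0% of FAP-like cells with a Pi16 UMI at 2 h and in 31.8% at 9 h, against 0.198% and 1.25% of the others. By the bound written in advance, an effect of the whole locus would put its measured neighbours at 4 times or more, and 0 of 1 measured within 100000 bp reached that: Tmem147 was 1.99 times as high (1.79 to 2.21). That bound was too strict, since Dmkn and Sbsn do not reach it either, and the ratio of Tmem147, which lies outside the 3 genes, is between theirs. From 1 neighbour, an effect of the locus cannot be told apart from an effect on the 3 genes by themselves.

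Of 10199 measured genes in order along the chromosomes, 89 were at least 4 times higher at 9 h in FAP-like cells, and 7 of these had another such gene next to them: Ccl2 with Ccl7, Ccl3 with Ccl4, and Cxcl3 with Cxcl1 and Cxcl2. Shuffled gene orders gave a median of 2 and a highest count of 12, and 80 of 10000 shuffles (0.8%) gave 7 or more. The bound set in advance, a count above the highest of the shuffles, was not passed, so chance order is not excluded by it, although chance gave so many in few shuffles. All 7 are chemokine genes of chromosomes 11 and 5, whose family members lie side by side. Ccl3 and Ccl4 in FAP-like cells were near the level of carried-over neutrophil RNA (217 of 247 and 253 of 340 CPM), and without them 5 genes had such a neighbour, and 3.68% of shuffles gave 5 or more.

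T or NK-like cells at 9 h showed Ccl2 at 970 CPM, but 97.4% of it was in the tenth of the 37 cells with the most. Ccl2 in unnamed cluster 18, which scored for both FAP and endothelial markers, was read from 61 cells at 9 h, and whether these are doublets was not tested.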
